A study of Homo sapiens with 12 samples.

How the data were processed

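Pull-down libraries were made from purified and annealed genomic DNA of HEK 293T cells with the ThruPLEX DNA-seq kit, and RNA libraries from poly(A) RNA with the VAHTS Stranded mRNA-seq kit. The 12 samples formed 6 groups of 2, and groups were taken from the labels. PDP is known here only by its code name.

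The submitters' processing notes name Trim Galore 0.4.4, Bowtie2 2.2.9, SAMtools 1.3.1, Picard, HOMER 4.9.1, HISAT2 2.0.5, Cufflinks 2.2.1 and GRCh38.p7. How these tools were set is not stated. The RNA tables have the columns of a Cuffdiff gene test, with 1 table per time point, and the authors' deposited values are FPKM pooled over the replicates of a condition. The authors' deposited p-value and q-value come from their test of PDP against control, with a call at q under 0.05. The score in the authors' deposited test statistic column was used only to derive a standard error, as log2 fold change divided by the statistic. The score in the authors' deposited peak list is an average over both replicates whose unit is not stated. Depth per library is unknown, because the tables hold pooled FPKM and the peak list holds no counts of reads.

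Log2 fold changes were computed as PDP over control from the deposited FPKM. The plan had been to take the authors' own fold change column, which holds text where PDP is at 0. A gene was expressed when the geometric mean FPKM of both conditions was at least 1. Of 58083 gene IDs, 56980 matched a symbol and 40177 had a biotype, and 28 symbols that had been turned into dates were restored by ID. Gene lists, settings and tests were chosen before the data were examined, except where stated. For each of 36 lists, the median log2 fold change of expressed members was placed among 10000 random lists matched in 20 expression bins (seed 1). Calls were counted over all genes and adjusted over the list alone by Benjamini-Hochberg on the authors' deposited p-value. Shared calls were tested by Fisher's exact test, two-sided, and 100 simulations of unchanged groups with a shared control gave the overlap that such a control makes.

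The rule for named genes was the 10 largest increases and the 10 largest decreases among called genes with a symbol and an FPKM of at least 1 in either condition at each time point, up to 4 called members per list by size of change, and 2 members of highest FPKM for a list with no call. It also took genes called in the same direction at all 3 time points and the 5 peaks of highest score. MT-CO1, MT-ND4 and the 3 h value of HSPA1A were chosen after their values were seen.

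No genome sequence and no gene strand were used, so the planned motif search was not run, shifted peaks did not avoid assembly gaps, and windows at transcription starts were replaced by distance to either end of a gene locus. Loci were those of the RNA tables, and end distances used loci that hold a single protein-coding gene. Peaks were assigned by their centre. Densities have exact Poisson intervals and ratios exact binomial intervals at 95%, which cover no more than counting error. A peak was counted at each locus end whose window held it, and windows of neighbouring loci could overlap. Such counts are not independent, so these intervals may be too narrow and the p-values of the ratios too small. Peaks were moved along each chromosome in 100 circular shifts. Because the peak list holds a score and no fold over input, the upper part by score stood in for the planned upper part by fold. Genes with and without a peak, and in loci over 100 kb and under 10 kb, were compared with draws matched on FPKM.

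Alternatives were a q of 0.01, a log2 change of at least 1, an FPKM minimum of 5 or none, a pseudocount of 1, the mean in place of the median, other windows and other locus lengths. Alternatives added after seeing the data were leaving out pseudogenes, genes alone in their locus, scaling to equal FPKM sums, and loci split by expression. The steps were tested on simulated data with 100 repeats. Lists of 20 unchanged genes fell outside the central 95% of random lists in 7% of repeats, and lists shifted by 0.2 and 0.5 were found in 64% and 100%. These lists were simulated for 3 h alone, with independent genes and a spread close to the SD of the 3 h changes (0.286). The SD was 0.596 at 24 h and 0.873 at 72 h, so such shifts are harder to find there. Work was done in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.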

Results

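HEK 293T is a human embryonic kidney line that carries the SV40 large T antigen. G-quadruplexes are four-stranded DNA structures formed by runs of guanine, and the series asked where a small molecule captures them in the genome of these cells and how transcripts change when a compound named PDP is added. The 12 samples fell into 6 groups of 2. A pull-down from purified and annealed genomic DNA and its input made up 2 groups, and the RNA groups were DMSO at 3 h and 1 µM PDP at 3 h, 24 h and 72 h. The RNA tables gave 1 pooled FPKM value per gene and condition for 58083 genes, so no library could be seen on its own, no SD between replicates could be given and the depth per library is unknown. Fold changes were therefore computed from the pooled FPKM values, and "called" means that the authors' deposited table gives the gene a q-value under 0.05. Standard errors (SE) of log2 fold changes are those implied by the statistic in the authors' deposited table. The labels do not say whether replicates came from separate cultures, so the p-values need not reflect the spread between cultures. How the authors' test estimated the spread is not stated. At 3 h NAV3 and DLG2 had the smallest p-value although their implied SE exceeded their log2 fold change. SE and p-value thus need not measure the same spread.

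The control was the same in all 3 RNA tables. Control values differed between the 3 h and 24 h tables by 1 constant factor of 1.04, with an SD of 0.000842 on the log2 scale over 13455 genes with FPKM above 1. The factor was 0.968 for the 72 h table (SD 0.000854, 13368 genes). Changes at 24 h and 72 h thus include any change over time in culture. Median log2 fold changes over all expressed genes were -0.0036 at 3 h, -0.031 at 24 h and 0.11 at 72 h. Scaling each condition to the same FPKM sum would add 0.17 at 24 h and -0.10 at 72 h to every gene, so some list medians are also given relative to all expressed genes.

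At 3 h few genes were called. The authors' deposited table called 17 genes, 16 higher and 1 lower with PDP, out of 14751 tested. All 17 sat at the smallest p-value it holds (5e-05, q = 0.0434), and 282 genes had an unadjusted p under 0.05. The median implied SE of expressed genes, 0.372, exceeded the robust spread of their log2 fold changes, 0.151. Few calls at 3 h thus need not mean that few transcripts differed. EHMT1 (ENSG00000181090.18, in a GRCh38 locus on chromosome 9 from 137605654 to 138124624), which encodes a histone H3 lysine 9 methyltransferase, went from 30.3 to 1137 FPKM, a log2 fold change of 5.23 (SE 0.32). RCCD1 went from 16.4 to 174 FPKM (log2 fold change 3.41, SE 0.34), and SAMD1, a protein that binds CpG islands, from 17.6 to 81.8 FPKM (2.22, SE 0.17). MGLL, which encodes monoglyceride lipase, went from 2.41 to 14.4 FPKM, ATP2A1, a calcium pump of the sarcoplasmic reticulum, from 1.49 to 11.4 FPKM, and the noncoding RNA PVT1 from 6.73 to 36.6 FPKM. NAV3 was also called, but its control value was 0.0334 FPKM and its implied SE, 19.3, exceeded its log2 fold change of 5.15. The other expressed genes in the EHMT1 locus had log2 fold changes of at most 0.19 in size. In the RCCD1 and ATP2A1 loci the largest size was 0.086 and 0.53. The pooled values cannot show whether a single library carried any of these increases. HSPA1B, an inducible HSP70 chaperone gene, was the gene called lower (64.9 to 35.8 FPKM). Its near-identical copy HSPA1A went from 8.10 to 6.45 FPKM, and was not called.

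Of the 17 genes, 9 were also called at 24 h in the authors' deposited table. EHMT1 was not among them and measured 28.7 FPKM against 31.4 in the control at 24 h, and 27.6 against 29.3 at 72 h. DLG2 and GNAZ were the 2 genes called higher at all 3 time points in the authors' deposited table. GNAZ, a G protein alpha subunit, had log2 fold changes of 0.82 (SE 0.31), 1.52 (SE 0.28) and 0.61 (SE 0.29). DLG2 stayed under 2 FPKM, and its implied SE was larger than its change at all 3 times (6.74 against 2.97, 6.56 against 3.19 and 7.12 against 3.96). HSPA1B turned from lower at 3 h to higher at 24 h (log2 fold change 1.32, SE 0.19) and 72 h (3.02, SE 0.19).

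Among the 17 genes called at 3 h, 5 were annotated as pseudogenes, among them RPL3P4 (21.7 to 49.7 FPKM), RPL13AP5 (25.3 to 47.9 FPKM) and BCLAF1P2. Such copies share sequence with their parent genes, so the origin of their reads is uncertain. Expressed pseudogenes, apart from those annotated as transcribed, had a median log2 fold change of 0.35 at 3 h (255 genes), 0.78 at 24 h (264 genes) and 0.15 at 72 h (229 genes). Transcribed pseudogenes, which include RPL13AP5, had medians of 0.04 at 3 h (204 genes, percentile 89.4), 0.16 at 24 h (211 genes, percentile 20.7) and 0.27 at 72 h (210 genes, percentile 79.3). Long noncoding RNA genes had medians of -0.01 at 3 h (508 genes, percentile 0.60), 0.33 at 24 h (568 genes, percentile 98.7) and 0.50 at 72 h (553 genes, percentile 100). Protein-coding genes had medians of -0.0066, -0.054 and 0.087. Pseudogenes of ribosomal protein genes had medians of 0.53 at 3 h and 1.03 at 24 h, where 17 of 57 were called higher, while the 48 ribosomal protein genes measured had medians of -0.07 and -0.08 and no member called. The medians of pseudogenes not annotated as transcribed lay at 3 h and 24 h above those of all 10000 random lists matched on expression (percentile 100), and at 72 h at percentile 12.1.

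**Figure D1:**
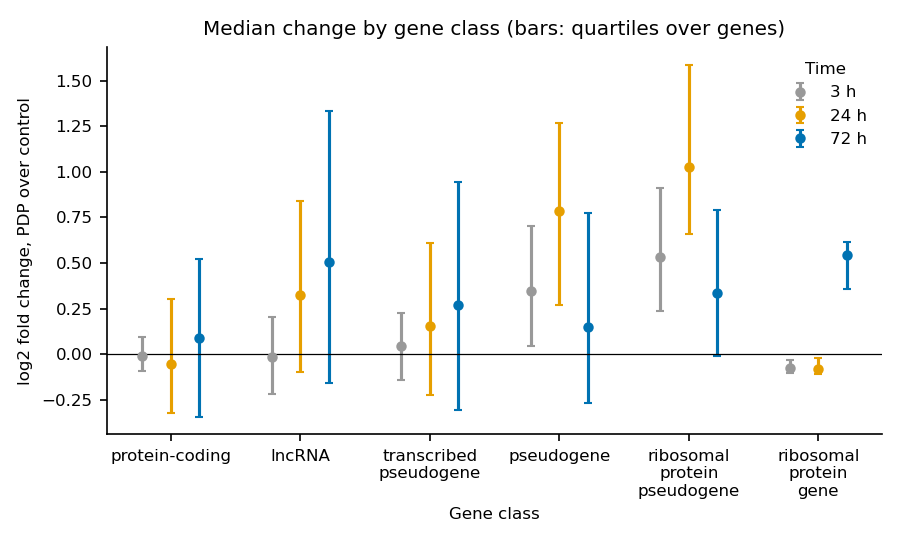
Median log2 fold change of FPKM with PDP over control (y axis) for classes of expressed genes (x axis) at 3 h, 24 h and 72 h, with bars for the quartiles over genes. Pseudogenes had medians of 0.35 and 0.78 at 3 h and 24 h, and protein-coding genes of -0.0066 and -0.054.

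At 24 h and 72 h many more genes were called, in comparisons that also include any change over time in culture. The authors' deposited tables called 2693 of 15385 tested genes at 24 h, 1417 higher and 1276 lower with PDP, and 4902 of 15423 at 72 h, 2935 higher and 1967 lower. The higher calls included more large changes: at 24 h 745 higher and 164 lower calls had a log2 fold change of at least 1 in size, and at 72 h the counts were 1550 and 810.

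**Figure D2:**
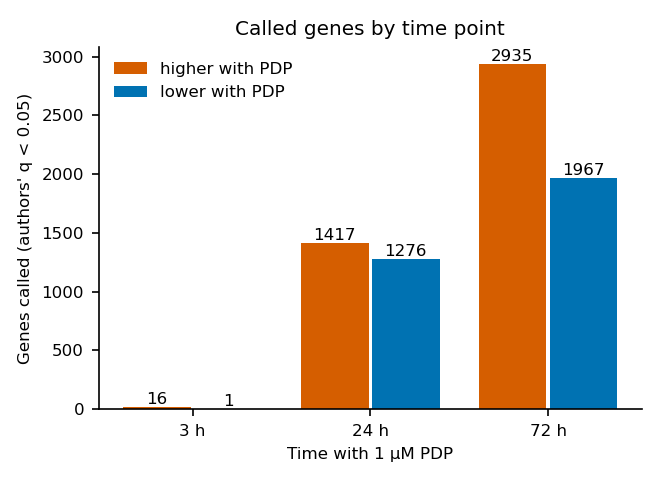
Number of genes called higher (orange) and lower (blue) with 1 µM PDP in the authors' deposited tables (y axis) at each time point (x axis). The bars rise from 16 and 1 at 3 h to 2935 and 1967 at 72 h.

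The largest increases at 24 h among called genes with FPKM of at least 1 in either condition were in genes of low expression in the control. LINC00173, a noncoding RNA, went from 0.394 to 10.1 FPKM (log2 fold change 4.68, SE 1.48). MYOD1, a muscle transcription factor, went from 0.228 to 1.90 FPKM, and NR5A2, a nuclear receptor, from 0.173 to 1.51 FPKM. FAM65B, SOWAHD, MEF2C-AS1 and PLEKHA6 were also among the 10 with the largest increases, between 2.97 and 3.49 on the log2 scale. Among the decreases, ATF5, a stress-responsive transcription factor, went from 24.2 to 3.89 FPKM (log2 fold change -2.64, SE 1.20). NCOA5 (ENSG00000124160.11, chromosome 20, 46060985 to 46089952), a nuclear receptor coactivator, fell from 35.9 to 8.81 FPKM (-2.03, SE 0.22). The other decreases included NPM2 (3.15 to 0.383 FPKM), POU2F2, PRR22, DOK3 and the small nucleolar RNA SNORD3A (19.9 to 3.26 FPKM), which a poly(A) library measures poorly.

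At 72 h the gene HIST2H2BE, a histone H2B gene, went from 0.286 to 17.9 FPKM (log2 fold change 5.97, SE 0.79). ANKRD37, a hypoxia-responsive gene, rose from 3.00 to 166 FPKM (5.79, SE 0.66), and MALAT1, an abundant nuclear noncoding RNA, from 12.8 to 491 FPKM (5.26, SE 0.42). FOS, a subunit of the AP-1 transcription factor, rose from 1.05 to 33.9 FPKM, HILPDA, a lipid droplet protein induced by hypoxia, from 24.7 to 748 FPKM, and HIST3H2BB from 0.189 to 10.3 FPKM. A poly(A) library measures the transcripts of HIST2H2BE and HIST3H2BB poorly, and how well it captured MALAT1 was not tested. CRYAB was called as well, with 0.0477 FPKM in the control and an implied SE of 13.6. NCOA5 fell at 72 h from 33.5 to 2.31 FPKM (-3.86, SE 0.31). LCMT2 fell from 9.48 to 0.748 FPKM and CYP27B1, the enzyme that makes active vitamin D, from 14.3 to 1.16 FPKM.

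Genes induced by hypoxia through HIF rose together. Of 20 measured list members, the authors' deposited table called 13 higher and none lower at 24 h (13 adjusted over the list alone), and all 20 higher at 72 h (20 adjusted over the list alone). Their median log2 fold change was -0.02 at 3 h, 0.68 at 24 h and 2.14 at 72 h, with percentiles among random lists of 29.7, 100 and 100. At 72 h DDIT4, an inhibitor of mTORC1 signalling, rose from 62.9 to 577 FPKM, NDRG1 from 23.5 to 163 FPKM and ADM, which encodes the vasoactive peptide adrenomedullin, from 15.2 to 103 FPKM. Glycolytic genes followed: 3 of 18 were called higher at 24 h (3 adjusted over the list alone, median 0.20) and 14 at 72 h (14 adjusted over the list alone, median 1.05), with none lower. ENO2 went from 9.20 to 165 FPKM at 72 h, GAPDH from 1801 to 4821 FPKM, PGK1 from 237 to 631 FPKM and ALDOC from 27.5 to 127 FPKM. The control of the 72 h table carried the values of the 3 h control.

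Immediate early genes, which cells induce within minutes of a stimulus, were called higher for 8 of 20 members at 24 h (9 adjusted over the list alone) and for 15 of 21 at 72 h (16 adjusted over the list alone), with 1 lower each time in the authors' deposited tables. Their medians were 0.56 and 1.53, both at percentile 100. At 72 h IER3 rose from 4.97 to 97.2 FPKM, ATF3 from 14.5 to 182 FPKM and JUNB from 8.28 to 97.9 FPKM. In the heat shock list, 3 members were called higher and 5 lower at 24 h (3 and 5 adjusted over the list alone, median -0.18, 17 measured), and 9 higher and 1 lower at 72 h (10 and 1 adjusted over the list alone, median 0.59, percentile 99.93). HSPA1B reached 511 FPKM at 72 h against 62.9 in the control, and the co-chaperone gene DNAJB1 198 against 45.4 FPKM, whereas DNAJA1 fell at 24 h from 138 to 60.5 FPKM.

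Splicing factor genes fell at 24 h. The authors' deposited table called 12 of 25 lower and none higher (18 adjusted over the list alone), and the median was -0.57 (percentile 0). SRSF6, a serine- and arginine-rich splicing factor, fell from 197 to 52.8 FPKM (log2 fold change -1.90, SE 0.20), and TRA2B, SRSF7 and SRSF2 fell by 1.08, 1.05 and 1.03 on the log2 scale. At 72 h 8 were called lower and 3 higher (8 and 3 adjusted over the list alone, median -0.23), and U2AF1, which binds the 3′ splice site, was among the higher (6.99 to 18.6 FPKM). GRCh38 holds a near-identical copy of this gene, so its value is uncertain.

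Genes of ribosome assembly fell at both later times while ribosomal protein genes rose at 72 h. In the ribosome biogenesis list, 10 of 25 members were called lower at 24 h (18 adjusted over the list alone, median -0.52) and 11 at 72 h (12 adjusted over the list alone, median -0.48), where 2 were higher. RRS1, needed for the large subunit, fell from 51.2 to 21.5 FPKM at 24 h and from 47.7 to 9.82 FPKM at 72 h, and NOP2, a nucleolar RNA methyltransferase, from 95.1 to 46.5 FPKM at 72 h. Of 48 ribosomal protein genes none was called at 24 h (0 adjusted over the list alone). Their median of -0.08 was -0.05 relative to all expressed genes and becomes 0.09 when the libraries are scaled to equal sums, and it lay at percentile 99.98 of random lists matched on expression (adjusted 0.0027). At 72 h 35 were called higher and none lower in the authors' deposited table (43 adjusted over the list alone), with a median of 0.54, which is 0.44 above that of all expressed genes. RPLP0, a protein of the large subunit's stalk, rose from 1473 to 2474 FPKM. Host genes of small nucleolar RNAs were called higher for 11 of 15 at 72 h (12 adjusted over the list alone, median 1.19, percentile 100) after 2 lower calls at 24 h (2 adjusted over the list alone, median -0.19). SNHG1 rose from 246 to 1698 FPKM, GAS5 from 376 to 1395 FPKM and TAF1D from 133 to 463 FPKM.

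Transcripts of the mitochondrial genome changed unequally. Of 13 measured, 8 were called lower at 24 h (9 adjusted over the list alone, median -0.76) and 9 at 72 h (9 adjusted over the list alone, median -1.46), with none higher in the authors' deposited tables. MT-ND6 (ENSG00000198695.2, mitochondrial bases 14149 to 14673) is encoded on the light strand. Its value fell from 698 to 293 FPKM at 24 h and from 651 to 18.5 FPKM at 72 h (log2 fold change -5.13, SE 0.30). The libraries were made from poly(A) RNA, and how well they captured the MT-ND6 transcript was not tested. MT-ND2 fell from 2790 to 965 FPKM and MT-ATP6 from 5963 to 1743 FPKM at 72 h. MT-CO1 had 9206 FPKM against 9312 in the control and MT-ND4 6139 against 5266 FPKM at 72 h, and neither was called. Among 31 nuclear genes of oxidative phosphorylation, 1 was called lower at 24 h (1 adjusted over the list alone) and 3 higher and 3 lower at 72 h (2 and 1 adjusted over the list alone).

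Genes of DNA replication and S phase fell at both later times: 13 of 28 were called lower and none higher at 24 h (15 adjusted over the list alone, median -0.39), and 15 lower and 2 higher at 72 h (16 and 2 adjusted over the list alone, median -0.42). UNG, uracil DNA glycosylase, fell from 96.9 to 42.9 FPKM at 24 h and from 90.3 to 32.4 FPKM at 72 h. CDC6, which loads the replicative helicase, fell from 57.6 to 21.7 FPKM at 72 h, and GINS3 from 34.4 to 9.51 FPKM, whereas CDT1 rose from 35.6 to 78.5 FPKM. Mitotic genes were called in both directions. Of 25, 9 were called lower and none higher at 24 h (11 and 1 adjusted over the list alone, median -0.33), and 12 higher and 4 lower at 72 h (13 and 4 adjusted over the list alone, median 0.40). The 24 h median lay at percentile 2.07 (adjusted over the 108 list medians 0.128), and it no longer passed with a pseudocount (percentile 2.945) or as a mean (8.67). The 72 h median lay at percentile 99.51 (adjusted 0.0407), and as a mean at 93.9. CCNB1, the mitotic cyclin B1, fell from 191 to 110 FPKM at 24 h and from 178 to 96.7 FPKM at 72 h, while TOP2A, topoisomerase II alpha, rose from 91.9 to 184 FPKM at 72 h. Of 9 measured replication-dependent histone genes, 5 were called higher at 72 h (5 adjusted over the list alone, median 2.65). The FPKM minimum uses the PDP value too, so genes that rise enter the list: 5 were measured at 3 h, 4 at 24 h and 9 at 72 h. With no FPKM minimum the 72 h median was 2.36. HIST1H1C rose from 5.46 to 68.7 FPKM. A poly(A) library measures replication-dependent histone transcripts poorly, so these values need not stand for all transcripts of these genes.

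Genes whose promoters are known for G-quadruplexes showed a mixed change. The authors' deposited tables called 6 of 21 higher and 1 lower at 24 h (8 and 2 adjusted over the list alone, median 0.27, percentile 99.54), and 8 higher and 1 lower at 72 h (8 and 1 adjusted over the list alone, median 0.19, relative to all expressed genes 0.08, percentile 71.0). MYC rose at 24 h from 281 to 425 FPKM (log2 fold change 0.60, SE 0.22) and had 227 FPKM against 262 in the control at 72 h, where it was not called. MYB, a transcription factor, rose from 1.32 to 4.52 FPKM at 24 h and from 1.23 to 8.50 FPKM at 72 h. PDGFA, a growth factor gene, rose from 1.90 to 4.84 FPKM at 24 h, and KIT, a receptor tyrosine kinase gene, from 5.57 to 10.2 FPKM. VEGFA rose from 31.8 to 141 FPKM at 72 h and also belongs to the hypoxia list. Of 28 proteins that bind or unwind G-quadruplexes, 5 were called lower at 24 h (5 adjusted over the list alone), among them the helicase gene DDX5 (408 to 237 FPKM), and 2 higher and 2 lower at 72 h (2 and 2 adjusted over the list alone). BLM, the Bloom syndrome helicase, fell at 72 h from 22.8 to 10.5 FPKM.

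The targets of p53 went both ways. In that list 4 of 24 were called higher and 3 lower at 24 h (5 and 3 adjusted over the list alone, median 0.20, percentile 95.3), and 8 higher and 6 lower at 72 h (10 and 6 adjusted over the list alone, median 0.24, relative to all expressed genes 0.14, percentile 81.3). HEK 293T cells express large T antigen, which binds p53. GADD45A rose from 23.8 to 76.3 FPKM at 72 h and MDM2 fell from 37.6 to 12.8 FPKM. In the list of double-strand break and replication stress repair, 3 of 29 were called lower at 24 h (3 adjusted over the list alone, median -0.19), and 7 lower and 1 higher at 72 h (6 and 1 adjusted over the list alone, median -0.04, relative to all expressed genes -0.15). BRCA2 fell from 14.0 to 4.92 FPKM and PALB2 from 9.16 to 4.59 FPKM at 72 h. At 3 h no member of these or any other of the 36 lists was called, except HSPA1B in the heat shock list (1 lower adjusted over the list alone). The telomere list had 1 higher and 2 lower calls at 24 h (1 and 2 adjusted over the list alone) and 3 higher and 1 lower at 72 h (2 and 1 adjusted over the list alone) among 17.

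**Figure D3:**
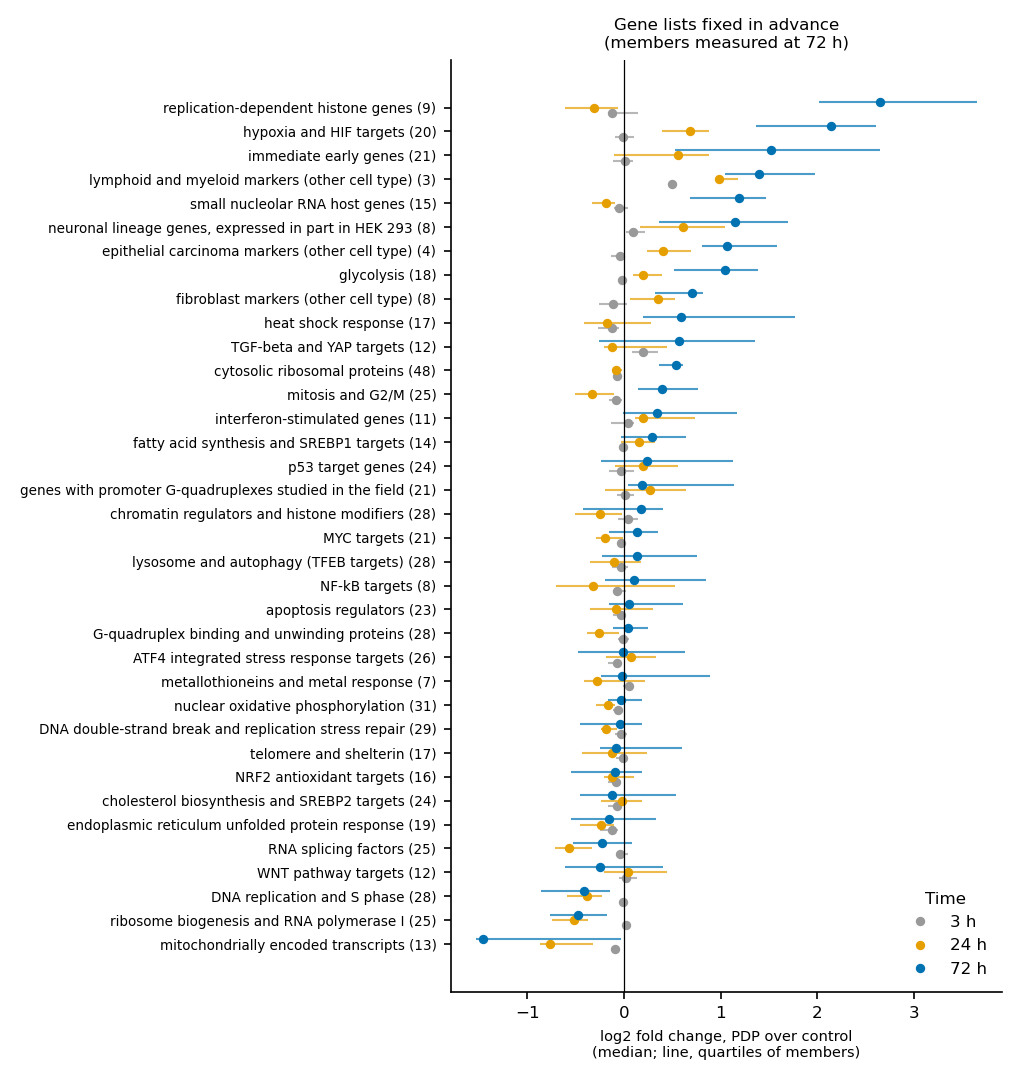
Median log2 fold change of FPKM with PDP over control (x axis) for each of 36 gene lists (y axis, with the members measured at 72 h) at 3 h, 24 h and 72 h, with lines for the quartiles of the members. Hypoxia genes lay at 2.14 and mitochondrially encoded transcripts at -1.46 at 72 h, and nearly all lists lay near 0 at 3 h.

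Across all 36 lists, 9 medians at 3 h, 14 at 24 h and 14 at 72 h lay outside the central 95% of random lists, and 5, 11 and 13 after Benjamini-Hochberg adjustment over the 108 medians. At 3 h the medians outside were small in size, the largest being 0.19 for TGF-beta and YAP targets and -0.13 for the heat shock list. These percentiles describe these libraries and are not a test across replicates.

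The 24 h and 72 h calls overlapped. Of 14805 genes tested in both tables, 899 were called higher in both against 258 for independent lists, and 783 lower in both against 169 (Fisher's exact test, two-sided, odds ratios 11.9 and 16.6), and 51 were called in opposite directions. Both tables use the same control, so independent lists are not what unchanged groups would give. At an unadjusted p under 0.05 in both tables, 2512 genes went the same way at 24 h and 72 h. Simulations of unchanged groups with a shared control gave 121. Their spread came from the 3 h changes (SD 0.286), which is smaller than at 24 h (0.596) and 72 h (0.873). Groups with unrelated changes could also exceed 121, so this count alone does not show sharing beyond the control. Across 13254 genes, which are not independent replicates, log2 fold changes at 24 h and 72 h had a Spearman's rho of 0.63. The simulated rho was 0.46 from the SD and from a robust spread, because control and both groups were given the same spread. A shared control alone need not give that rho here. The covariance of the 24 h and 72 h changes was 0.315 against 0.0412 simulated, or 0.0208 from a robust spread. The covariance between 3 h and 24 h was 0.0475, against 0.0371 simulated from the SD of the 3 h changes and 0.0205 from a robust spread. Between 3 h and 72 h it was 0.0370, against 0.0357 and 0.0190, so the excess depends on the spread assumed. At an unadjusted p under 0.05 in both tables, 102 genes at 3 h and 24 h and 67 at 3 h and 72 h went the same way, under the 121 simulated. The 3 h table gave 282 of 14751 genes such a p, fewer than the simulation assumes, so whether 3 h changes were shared beyond the control stays open. Calls at 3 h and 24 h shared 8 higher genes against 1.32 for independent lists (exact p = 1.26e-05, adjusted over 6 tests 2.52e-05), and those at 3 h and 72 h shared 6 against 2.81 (exact p = 0.0461, adjusted 0.0692), without allowance for the shared control. Without genes annotated as pseudogenes, 4 genes were called higher at both 3 h and 24 h. They include RP11-475C16.1, which had no biotype, and DLG2, whose implied SE exceeded its change.

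The pull-down list held 51446 peaks, with a median width of 406 bases. It holds only peaks found in both replicates of annealed genomic DNA, so its size does not show how far these agreed. The highest serial numbers in the replicates' peak names summed to 250438 and 215232, so each replicate's own list appears to have been longer. Between replicates the serial numbers had a median Spearman's rho of 0.584 over 23 chromosomes. The peak with the highest score by far, 7302 on the authors' scale against a median of 11.0, lay on the mitochondrial genome from base 212 to 766, across the end of the noncoding control region and the genes MT-TF and MT-RNR1. Next came peaks on the short arm of chromosome 21 at 8234309 to 8234711 (score 1538), at 8219803 to 8220205 (score 417, in a locus that holds the 5.8S ribosomal RNA gene RNA5-8S5) and at 8419993 to 8420653 (score 290). The fifth was on chromosome 2 at 32916116 to 32916518, in the locus of the noncoding RNA gene LINC00486 (score 242). The score has no stated unit, and the list holds no fold over input. Mitochondrial DNA and ribosomal RNA genes are present in many copies, so this ranking need not follow the strength of capture. Coordinates are GRCh38, as the submitters' processing notes name it.

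Gene loci held 57.5% of the 51379 peaks on the autosomes and chromosome X (95% exact binomial interval 57.1% to 57.9%, counting error only). In 100 circular shifts of the peaks along their chromosomes, which could not avoid assembly gaps, the share was 52.9% at the median and 54.5% at most. Around 7201 loci that hold a single protein-coding gene, peaks were rarer at the ends. There were 11.4 peaks per megabase within 500 bases of a locus end against 23.0 per megabase at 20 to 50 kb outside, a ratio of 0.498 (95% exact interval 0.423 to 0.584, 157 peaks near ends). The ratio was 0.366 (0.281 to 0.469) for 3647 loci of genes with a control FPKM of at least 1 and 0.656 (0.529 to 0.805) for 3554 loci under it. Density at the ends differed between these by a ratio of 0.594 (0.425 to 0.826, exact binomial p = 0.00133, adjusted over 13 tests 0.00173). With a window of 2000 bases outside and 500 inside, the ratio was 0.954 (0.884 to 1.03) over all loci, 0.820 (0.734 to 0.914) at loci of expressed genes and 1.11 (1.00 to 1.23) at the others, and between 1000 and 5000 bases outside density was 1.16 times that of the flank. Start and end of a gene could not be told apart, because gene strand was not used here.

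**Figure D4:**
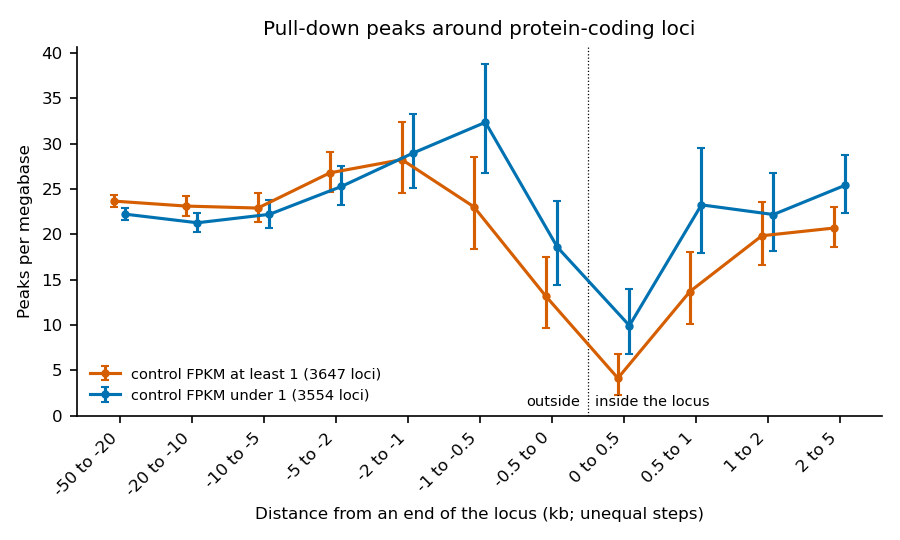
Pull-down peaks per megabase (y axis) by distance from an end of a locus with a single protein-coding gene (x axis, unequal steps; negative values lie outside), for genes with control FPKM of at least 1 (orange) and under 1 (blue), with 95% exact Poisson intervals. Just inside the ends, from 0 to 0.5 kb, density was 4.12 and 9.93 per megabase against 23.7 and 22.2 at 20 to 50 kb outside.

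None of the 22 genes listed for promoter G-quadruplexes had a peak within 1000 bases of either locus end. Among expressed genes in loci with a single protein-coding gene, 200 of 3741 (5.35%) had such a peak, which gives 1.18 for 22 genes, so a count of 0 is not unusual (binomial probability 0.299). The loci of 9 of the 22 hold more than 1 gene, and their ends need not be those of the listed gene. The nearest peak lay 1490 bases from an end of the VEGFA locus (chromosome 6, 43770184 to 43786487), and 8718 bases from an end of the MYC locus (chromosome 8, 127735434 to 127741434). Inside their loci, 14 of the 22 held 30 peaks in all, among them MET with 5, RB1 and HSP90AA1 with 4 each and TERT with 2.

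Whether genes with a peak near a locus end passed the percentile limits depended on the distance allowed, and so did the number of genes. The difference in medians was above 0 at 24 h and 72 h for each distance. At 24 h, 200 expressed genes with a peak within 1000 bases of a locus end had a median log2 fold change of 0.06, against -0.06 for 3541 without and -0.0015 in draws matched on expression (percentile 95.1). Of these genes 15.0% were called higher against 13.3% (Fisher's exact p = 0.521, two-sided), and 11.5% lower against 13.8% (Fisher's exact p = 0.398). At 72 h the medians were 0.12 and 0.07 (matched 0.08, percentile 78.0), with 28.7% against 24.7% called higher (Fisher's exact p = 0.233) and 15.4% against 19.4% lower (Fisher's exact p = 0.191). At 3 h, 193 genes with a peak had a median of -0.02 against -0.0041 (percentile 13.7). Genes with a peak within 5000 bases passed at both later times, at percentile 100 each. At 24 h 1283 had a median of 0.0071 against -0.07 (matched -0.07), and at 72 h 1267 had 0.11 against 0.05 (matched 0.05). The differences in median, 0.0812 and 0.0626, compare with 0.120 and 0.0429 within 1000 bases, where fewer genes had a peak. With a peak anywhere in the locus, 10.1% of 1482 genes were called lower against 16.0% of 2259 at 24 h (Fisher's exact p = 2.33e-07), and 15.5% against 21.5% at 72 h (Fisher's exact p = 4.68e-06). Adjusted over the 42 such tests of all settings, these were 9.77e-06 and 9.83e-05. A longer locus has more room for a peak, and locus length was not matched. Long loci also had fewer lower calls than short ones, so peak and locus length cannot be told apart here. Genes in loci over 100 kb had a median of 0.15 at 24 h against -0.05 for loci under 10 kb (341 and 910 genes, percentile 99.2), but short loci matched on expression had a median of 0.08. At 72 h the medians were 0.21 and 0.12 (matched 0.11, percentile 98.5), and at 3 h 0.03 and -0.02 (matched -0.0066, percentile 99.99). With loci over 200 kb and under 5 kb none of these passed (percentiles 69.4, 89.7 and 76.7 at 3 h, 24 h and 72 h). There were then only 81, 83 and 85 long loci. The differences in median were 0.0381, 0.215 and 0.141, against 0.0508, 0.195 and 0.0902 with the main lengths. Of genes in long loci 12.02% were called higher and 4.69% lower at 24 h, against 16.6% and 16.4% in short loci. At 72 h these shares were 25.4% and 9.28% against 30.9% and 21.6%, and the differences in share were not tested or matched on expression.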

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

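The tests of parents' reads on pseudogenes were set out before their results were seen, and the other tests in this part were chosen after the result was seen. A peak on the mitochondrial genome, outside the gene comparisons, had a score of 7302. There were 64 peaks on unplaced contigs, which the comparisons also left out.

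Genes annotated as pseudogenes, apart from transcribed ones, were higher with PDP at 3 h and 24 h. Among 171 pseudogenes matched by symbol to 134 parents, the median log2 fold change at 24 h was 0.85, while the upper quartile of the parents was -0.0450, which argues against a rise in the parents' own transcripts. Genomic DNA in the 3 h libraries would have raised lncRNA genes to a median of 0.47, and the upper bound of their median was 0.0266; at 24 h the lncRNA median was 0.33, so DNA in those libraries stays open. Pseudogene changes rose with the control FPKM of the parent (Spearman's rho across genes 0.185 at 3 h, permutation p = 0.018, and 0.259 at 24 h, permutation p = 0.00078). The permutations took pseudogenes as independent, although some share a parent (163 for 127 parents at 3 h), so these p-values may be too small. A larger share of parents' reads placed on copies may contribute, and a change of the pseudogenes' own transcription with PDP stays open, untested.

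Hypoxia genes were higher with PDP at 72 h. Scaling to equal FPKM sums adds -0.10 to every gene at 72 h, which left their median at 2.04. A difference in FPKM sums of that size thus cannot explain the rise, but no other form of scaling was tested. The control of the 72 h table differs from the 3 h control by a constant with an SD of 0.000854, so PDP and time in culture cannot be told apart for this list: a dense culture short of oxygen is a candidate explanation, and so is PDP.

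Pull-down peaks were fewer at the ends of gene loci. A loss at the transcription start alone would leave at least 0.5 of the density over both ends, and at loci of expressed genes the upper bound was 0.469 within 500 bases, which argues against it, but 0.661 within 1000 bases. These bounds may be too low, because a peak was counted at each locus end whose window held it. At the other loci the ratio within 500 bases was 0.656 with an upper bound of 0.805, so such a loss may account for it there. Within 1000 bases their ratio was 0.987 (0.865 to 1.12), so no loss was seen over that window. Loss of GC-rich fragments could also give the ratio of 0.498 at all loci and cannot be told apart here, because no sequence was used. No biological explanation was tested.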

How the results depend on the processing

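The alternatives without pseudogenes, with genes alone in their locus, with equal FPKM sums and by expression of the locus were chosen after the data were seen. No paired analysis was possible because the tables hold 1 pooled value per condition, which also ruled out leaving out a replicate; the 3 motif alternatives were not run. Of 430 alternative list medians 406 kept their side of the percentile limits, 13 no longer passed and 11 newly passed; 25 changed sign, 1 of them for a list outside the limits. Equal FPKM sums add 1 constant to every gene and cannot move a percentile; they changed the sign of 24 of 108 medians, 2 of them outside the limits. Lists outside the limits numbered 37 of 108, and 33 to 39 under the alternatives. The medians outside the limits that changed sign were those of cholesterol genes at 24 h (0.0613 as a mean and 0.147 with equal sums, against -0.02) and of ribosomal proteins at 24 h (0.0869 with equal sums). Of 61 other alternatives 38 kept their result, apart from 7 settings in which a constant left it as it was. In the authors' deposited tables, calls with q under 0.01 numbered 0 at 3 h, where the smallest p-value gives q = 0.0434 and 282 genes had an unadjusted p under 0.05, and 1522 at 24 h. Calls with a log2 change of at least 1 numbered 10, 909 and 2360 at 3 h, 24 h and 72 h, calls of genes alone in their locus 8, 1238 and 1973, and protein-coding calls at 3 h 10; each of these counts fewer genes by construction. Shared calls with q under 0.01 numbered 0 for 3 h with 24 h, 0 for 3 h with 72 h and 932 for 24 h with 72 h, and 4 without pseudogenes for 3 h with 24 h. The ratio of peaks at locus ends was 0.954 with the window of 2000 bases outside and 500 inside. The difference in median log2 fold change by peak passed with a peak within 5000 bases (0.0812 at 24 h, 0.0626 at 72 h) or anywhere in the locus (0.139 and 0.0646). Within 1000 bases it was 0.120 and 0.0429, with fewer genes, and did not pass. The difference by locus length no longer passed with loci over 200 kb and under 5 kb (0.0381, 0.215 and 0.141 at 3 h, 24 h and 72 h), nor with a pseudocount of 1 at 72 h (0.0553). With the main lengths it was 0.0508, 0.195 and 0.0902, from more loci. The cause was not tested for the peak and length differences. Depth per library is unknown, so what it limits cannot be given.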

Other observations

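In the cholesterol list of 24, the authors' deposited tables called 3 higher and 4 lower at 24 h (4 and 4 adjusted over the list alone), and 7 higher and 5 lower at 72 h (8 and 6 adjusted over the list alone). INSIG1, which retains SREBP in the endoplasmic reticulum, rose from 108 to 261 FPKM at 24 h and from 101 to 467 FPKM at 72 h, while NSDHL fell from 44.0 to 19.3 FPKM at 72 h. Of 14 fatty acid synthesis genes 1 was called higher and none lower at 24 h (0 adjusted over the list alone, median 0.16, percentile 99.61, adjusted 0.0351), and 3 higher and none lower at 72 h (3 adjusted over the list alone), among them SCD, a fatty acid desaturase (227 to 334 FPKM). In the unfolded protein response, 4 of 19 were called lower at 24 h (4 adjusted over the list alone), and 3 higher and 6 lower at 72 h (4 and 8 adjusted over the list alone). HSPA5, the chaperone BiP, rose from 162 to 808 FPKM at 72 h. Of 26 ATF4 targets, 5 were called higher and 1 lower at 24 h (6 and 1 adjusted over the list alone), and 6 and 6 at 72 h (7 and 6 adjusted over the list alone). PPP1R15A, a phosphatase subunit acting on eIF2 alpha, rose from 6.56 to 58.2 FPKM at 72 h. Of 16 NRF2 targets, 1 was called higher at 24 h (1 adjusted over the list alone), and 2 higher and 4 lower at 72 h (2 and 6 adjusted over the list alone); HMOX1, heme oxygenase, rose from 11.5 to 31.9 FPKM. Of 7 metal response genes, 1 was called higher and 2 lower at 24 h (1 and 2 adjusted over the list alone), and 2 and 1 at 72 h (2 and 1 adjusted over the list alone), with MT1X, a metallothionein, rising from 70.0 to 283 FPKM.

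In the authors' deposited tables, interferon-stimulated genes had 1 of 11 called higher and none lower at 24 h (1 adjusted over the list alone) and 5 at 72 h (5 adjusted over the list alone), with IFITM1 rising from 20.3 to 44.6 FPKM. NF-kB targets had 1 higher and 2 lower of 7 at 24 h (2 and 2 adjusted over the list alone) and 2 higher of 8 at 72 h (2 adjusted over the list alone); NFKBIA, the inhibitor of NF-kB, fell from 14.9 to 7.62 FPKM at 24 h. MYC targets had 2 higher and 4 lower of 21 at 24 h (3 and 4 adjusted over the list alone) and 4 higher and 1 lower at 72 h (4 and 1 adjusted over the list alone). Lysosome and autophagy genes had 3 higher and 1 lower of 28 at 24 h (3 and 1 adjusted over the list alone) and 9 higher and 1 lower at 72 h (9 and 1 adjusted over the list alone), among them GABARAPL1, an autophagosome protein (16.0 to 44.9 FPKM). Apoptosis regulators had 2 higher and 5 lower of 24 at 24 h (3 and 5 adjusted over the list alone) and 6 higher and 4 lower of 23 at 72 h (7 and 4 adjusted over the list alone), with BBC3, a BH3-only protein, rising from 4.04 to 12.1 FPKM. WNT targets had 1 higher and 1 lower of 13 at 24 h (1 and 1 adjusted over the list alone) and 3 higher and 2 lower of 12 at 72 h (3 and 4 adjusted over the list alone); CCND1, cyclin D1, fell from 52.8 to 22.5 FPKM. TGF-beta and YAP targets had 2 higher and 1 lower of 11 at 24 h (2 and 1 adjusted over the list alone) and 5 higher of 12 at 72 h (5 higher and 1 lower adjusted over the list alone). Chromatin regulators had 3 higher and 7 lower of 28 at 24 h (3 and 10 adjusted over the list alone) and 6 higher and 4 lower at 72 h (6 and 4 adjusted over the list alone); BRD2, a bromodomain protein, rose from 251 to 877 FPKM at 72 h and EP300, a histone acetyltransferase, fell from 30.8 to 17.1 FPKM.

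All measured members of the 4 lists of lineage markers lay above 0 at 72 h: 8 neuronal, 8 fibroblast, 3 lymphoid and myeloid and 4 epithelial genes, with median log2 fold changes of 1.14, 0.71, 1.39 and 1.07 and percentiles of 99.48, 98.41, 91.2 and 97.4 (adjusted 0.0416, 0.107, 0.351 and 0.148). The FPKM minimum uses the PDP value too, which favours members that rose, and with no minimum the neuronal median was 0.76 at percentile 95.3. Neuronal genes, which HEK 293T cells express in part, had 2 of 8 called higher at 24 h (2 adjusted over the list alone) and 2 at 72 h (3 adjusted over the list alone); the neurofilament gene NEFL rose from 22.4 to 102 FPKM at 72 h in the authors' deposited table. Fibroblast markers had 0 of 8 called at 24 h (0 adjusted over the list alone) and 4 higher at 72 h (5 adjusted over the list alone), with FN1, fibronectin, rising from 6.63 to 21.7 FPKM and VIM, vimentin, from 251 to 399 FPKM. Lymphoid and myeloid markers had 1 of 3 called higher at 24 h (1 adjusted over the list alone) and 0 at 72 h (0 adjusted over the list alone). Epithelial carcinoma markers had 1 of 4 called higher at 24 h (1 adjusted over the list alone) and 2 at 72 h (4 adjusted over the list alone), with KRT8, a keratin, rising from 34.5 to 83.8 FPKM.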
